A study of Arabidopsis thaliana with 12 samples.

How the data were processed

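Total RNA from lyophilized rosette leaves was amplified, labelled with Cy5 and hybridised to CombiMatrix oligonucleotide arrays, per the labels' protocols. The plants were grown at 70% relative humidity, 24 °C by day and 22 °C by night, and an irradiance of 100 to 120 µE, per the labels. The 12 arrays fall into wild type and the GmENOD40 lines 1.1, 3.1 and 4.4, with 3 arrays each, as the sample titles state. Each array carried a pool of leaves of 8 plants, and nothing in the labels says whether the pools were grown as separate sets of plants, so the p-values measure only the spread between these pools and arrays.

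The authors deposited 1 scanner file per array and a series value table. The scanner files give, per the file headers, the foreground intensity of each of 94928 spots as the median and the mean over its pixels, together with the probe sequence and a flag for spots that were left out. They hold no local background, and the gene name field was empty on all 12 arrays. The scanner software and its settings are not given in the sources used here. The authors' value table holds linear intensity per probe. Set against the scanner files, the ranks of each column followed those of the median over unflagged spots with a Spearman correlation of at least 0.999999, and the column medians ran from 422 to 423, as between-array quantile normalization without background subtraction leaves them. That step is inferred from the values and is not stated in the sources used here. The table lists 27763 Arabidopsis probes, of which 26679 have a value on all 12 arrays.

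The main values were computed from the pixel medians. Flagged spots, 160 to 729 per array, were set to missing. Background was corrected by normexp with an offset of 50, fitted to the foreground signal of all spots since no local background is given. Arabidopsis spots were then quantile normalized between arrays and taken to log2, and the replicate spots of a probe were averaged. There were 27638 probes with 3 spots, 124 with 4 and 1 with 5. Control spots were left out of the tests, and dim probes were kept. The offset shrinks the fold changes of dim probes. A probe counted as above background on an array when its mean raw signal exceeded the 95th percentile of the negative control spots there. Where a probe was not above background on any array of a group, and for Ath_20_3541 also where 1 array of the dimmer group was above it, the fold is a bound: the mean of the brighter group against the mean over arrays of the higher of the probe's own value and the lowest value among probes above background, all as normalized log2 values.

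Probes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table. All 12 arrays entered 1 fit with group as the only term, since 3 arrays per group leave few degrees of freedom. The contrasts were each line against wild type, the mean of the 3 lines against wild type, and a moderated F test among the lines. All tests were two-sided, with Benjamini-Hochberg adjustment over 27763 probes and a threshold of 0.05. Standard errors are those of the moderated fit. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

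No slide number or scan date was given. Arrays were assigned to physical chips from the data by joining arrays that shared at least 60% of the dark spots of the smaller set. Positions shared in this way were taken as properties of the array surface, since CombiMatrix arrays can be stripped and hybridised again. The chip was used as a fixed block in an alternative fit, and differences between a line and the wild-type array of the same chip were taken where both were present. The order in which the samples were hybridised is not given in the sources used here.

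The fit was tested on simulated data before use, with the probe means and spreads of the real arrays and 200 probes changed in all 3 lines, in 20 runs over 27763 probes. For 1 line against wild type it recovered 55.4% of the changes of 1 log2 unit and 93% of those of 2 log2 units, and 5.36% of its calls were false. For the average of the 3 lines it recovered 71.3% and 96.6%, with 5.22% false calls. The average with chip as a block recovered 53.5% and 93.6%. The simulated arrays held no differences between chips, so these shares do not cover data in which chips differ.

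The reference supplied pairs locus tags with gene symbols and holds no sequences, and the files do not pair the probes with loci, so no probe could be assigned to a gene. The 26 gene lists fixed before the data were examined, with 474 members on glucosinolates, cell wall enzymes, hormones, photosynthesis and other leaf functions, were therefore not tested. The rule fixed for named genes counts probes with no gene name and names none. The 4 probes printed are its first 2 in each direction for the average of the lines: among called probes with all 9 overexpressor arrays on the same side of all 3 wild-type arrays, those with the largest log2 fold changes. Printing them falls outside the rule and was decided after their values were seen. Their sequences are those of the scanner files. None of them shares a stretch of 20 bases with another probe, as 261 of the 27763 probes do.

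Alternatives fixed before the data were examined were no background subtraction, plain subtraction, 75th percentile scaling, cyclic loess, a filter on dim probes, the authors' value table, replicate number as a block, chip as a block, fits with only the groups compared, an intensity trend in the prior variance, array weights, a minimum of 2-fold, the median over replicate spots for line 1.1, 1 mean per line as the replicate, and leaving out each array in turn. Plain subtraction used the median of the negative control spots of each array, since no local background is given. Chip as a random block, leaving out chip D, leaving out chip D and replicate 1 of line 4.4 together, the pixel mean, and the median over replicate spots for the remaining comparisons were added after seeing the data.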

Results

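Gene expression was measured in rosette leaves of Arabidopsis thaliana, ecotype Wassilewskija, in wild-type plants and in 3 independent transgenic lines named 1.1, 3.1 and 4.4. Each line carried the soybean early nodulin gene GmENOD40 behind the constitutive 35S promoter of cauliflower mosaic virus. ENOD40 genes are induced early in the formation of nitrogen-fixing root nodules of legumes and give rise to transcripts with very short open reading frames. The plants grew in soil under 10 h light and 14 h dark. Each of the 4 groups was represented by 3 arrays, and each array carried RNA from a pool of rosette leaves of 8 plants. The comparison of each line with wild type asks which leaf transcripts differ when GmENOD40 is overexpressed, and the comparison among lines asks whether independent insertions of the construct differ.

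The arrays were 1-colour oligonucleotide arrays with 27763 Arabidopsis probes, most of them spotted 3 times. The median raw intensity over Arabidopsis spots lay between 500.5 and 780 on the 12 arrays. Between 6175 and 11614 probes per array (22.2% to 41.8%) exceeded the 95th percentile of that array's negative control spots, and 14616 probes did so on none of the 12 arrays. The files do not pair the probes with genes, so the changes are given as probe counts, and 4 probes are identified by name and sequence. No probe was named for the soybean transgene, so its own level was not measured here. The number of arrays limits the precision, with a median standard error over probes of 0.20 on the log2 scale for 1 line against wild type and 0.16 for the average of the lines.

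Dark spots, defined as spots more than 1.5 log2 units below the median of their probe, recurred at the same positions on different arrays. They sorted the 12 arrays into 4 sets, taken as physical chips and here named A to D, each carrying between 2 and 4 of the hybridised samples. The 13 pairs of arrays on the same chip shared 69% to 99.6% of the smaller set of dark spots, and the other 53 pairs shared 0% to 55.9%. Of those, pairs with 1 array on chip D shared 0%, and pairs between chips A, B and C 38.4% to 55.9%. Dark spots can thus recur without a shared chip. Pairs within chip D rest on 24 to 29 shared spots (69% to 89.7%), against 97.4% or more within the other chips. Chips A, B and C each held 1 wild-type array. Chip D held replicate 1 of line 1.1, replicate 3 of line 3.1 and replicate 2 of line 4.4, and no wild-type array. These arrays had the fewest probes above background, 7005, 7863 and 6175 in that order, against 10280 to 10852 on the wild-type arrays. In a limma fit with group and chip as terms, 4394 probes (15.8%) differed among chips and 49 (0.176%) among the 4 groups, both at Benjamini-Hochberg adjusted p under 0.05. Values with chip as a block are therefore given beside those of each comparison, and bounds between arrays of the same chip for 3 of the named probes.

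**Figure D1:**
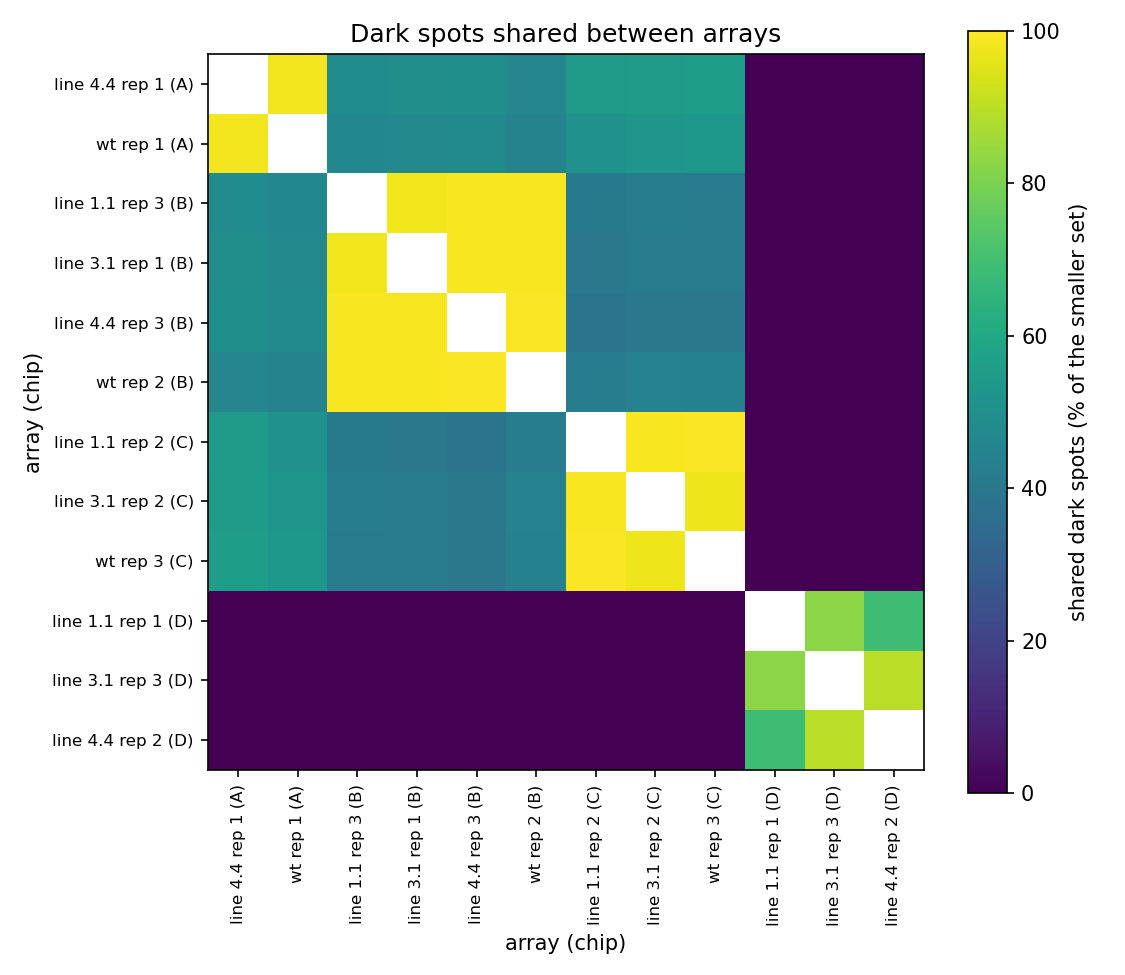
Dark spots shared by each pair of the 12 arrays, as a percentage of the smaller of both sets, with arrays ordered by chip (letter in brackets) on both axes. The 13 pairs within a chip lie at 69% or above, and the 3 arrays of chip D stand apart from the 9 others.

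In the average of the 3 overexpressing lines, 108 of the 27763 probes differed from wild type (limma, adjusted p under 0.05), 54 of them higher and 54 lower. With probes whose dimmer group was above background on no array taken at their bound (18 probes), and 8 given no size because both groups lay below background or the bound was under 1, the median rise was 2.18-fold and the median fall 1.88-fold, and 48 of the 108 changed by at least 2-fold. Of the called probes, 95 lay above background on at least 3 arrays.

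The largest rise by fitted log2 fold change was at probe Ath_20_21735 (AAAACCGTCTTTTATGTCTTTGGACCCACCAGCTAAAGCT), with a normalized log2 intensity of 11.56 ± 0.18 (SD, n = 9) in the overexpressors against 8.15 ± 0.20 (SD, n = 3) in wild type. Its log2 fold change was 3.41 (SE 0.13, limma adjusted p = 2.05e-07). It was higher in 9 of 9 overexpressor arrays than in any wild-type array, which the rule for naming it requires. This probe was above background on all 9 overexpressor arrays and not above background on any of the 3 wild-type arrays, so the rise is a bound of at least 6.47-fold. The fitted log2 fold changes of the named probes use values at background and are not sizes where a bound is given. Between arrays of the same chip the bound for this probe ran from 5.17-fold to 8.37-fold across the 6 such pairs of line and wild type. Probe Ath_20_10482 (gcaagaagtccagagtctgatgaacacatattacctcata) rose by 2.50 on the log2 scale (SE 0.23; limma adjusted p = 0.000641), to 11.36 ± 0.95 (SD, n = 9) from 8.86 ± 0.51 (SD, n = 3). It too was not above background on any wild-type array, which gives at least 5.18-fold, and it was above background on 8 of the 9 overexpressor arrays. Its same-chip bounds ran from 2.93-fold to 12-fold.

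Probe Ath_20_3541 (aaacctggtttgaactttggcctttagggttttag) was the first among the probes called lower, ranked by a fitted log2 fold change of -2.63 (SE 0.24; limma adjusted p = 0.000725). It stood at 11.21 ± 0.11 (SD, n = 3) in wild type, above background on all 3 arrays, and at 8.58 ± 0.48 (SD, n = 9) in the overexpressors, where it was above background on 1 of 9 arrays, so the fall is a bound of at least 3.76-fold. Its same-chip bounds ran from 3.51-fold to 5.52-fold. Probe Ath_20_1250 (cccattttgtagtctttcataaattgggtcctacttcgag) was the next in order among the probes called lower (limma adjusted p = 0.000135). It was above background on 1 of the 12 arrays only, and its bound of 0.977-fold does not exceed 1, so no size of change is given for it. Both probes were lower in 9 of 9 overexpressor arrays than in any wild-type array, which the rule for naming them requires.

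With chip as a block, limma called 134 probes in the average of the lines, 69 higher and 65 lower, of which 85 were among the 108. The first 3 named probes had blocked log2 fold changes of 3.45, 2.60 and -2.64 in the order given. The count depended on single arrays: it was 19, 17 and 20 without wild-type replicates 1, 2 and 3, 70, 58 and 42 without replicates 1, 2 and 3 of line 1.1, and 46, 34 and 61 without those of line 3.1. It was 26 with plain background subtraction, at which probes Ath_20_10482 and Ath_20_3541 were no longer called, and 45 with 75th percentile scaling. With 1 mean per line as the replicate it was also 45, of which 31 were among the 108, and probe Ath_20_10482 was no longer called. Array weights raised it to 2238, with all 108 included, and chip as a random block to 233. The even split by direction depended on the setting: 54 were higher and 20 lower without chip D, 29 and 13 with replicate number as a block, 18 and 8 with plain subtraction, 15 and 4 without wild-type replicate 1, and 45 and 75 without replicate 3 of line 4.4.

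**Figure D2:**
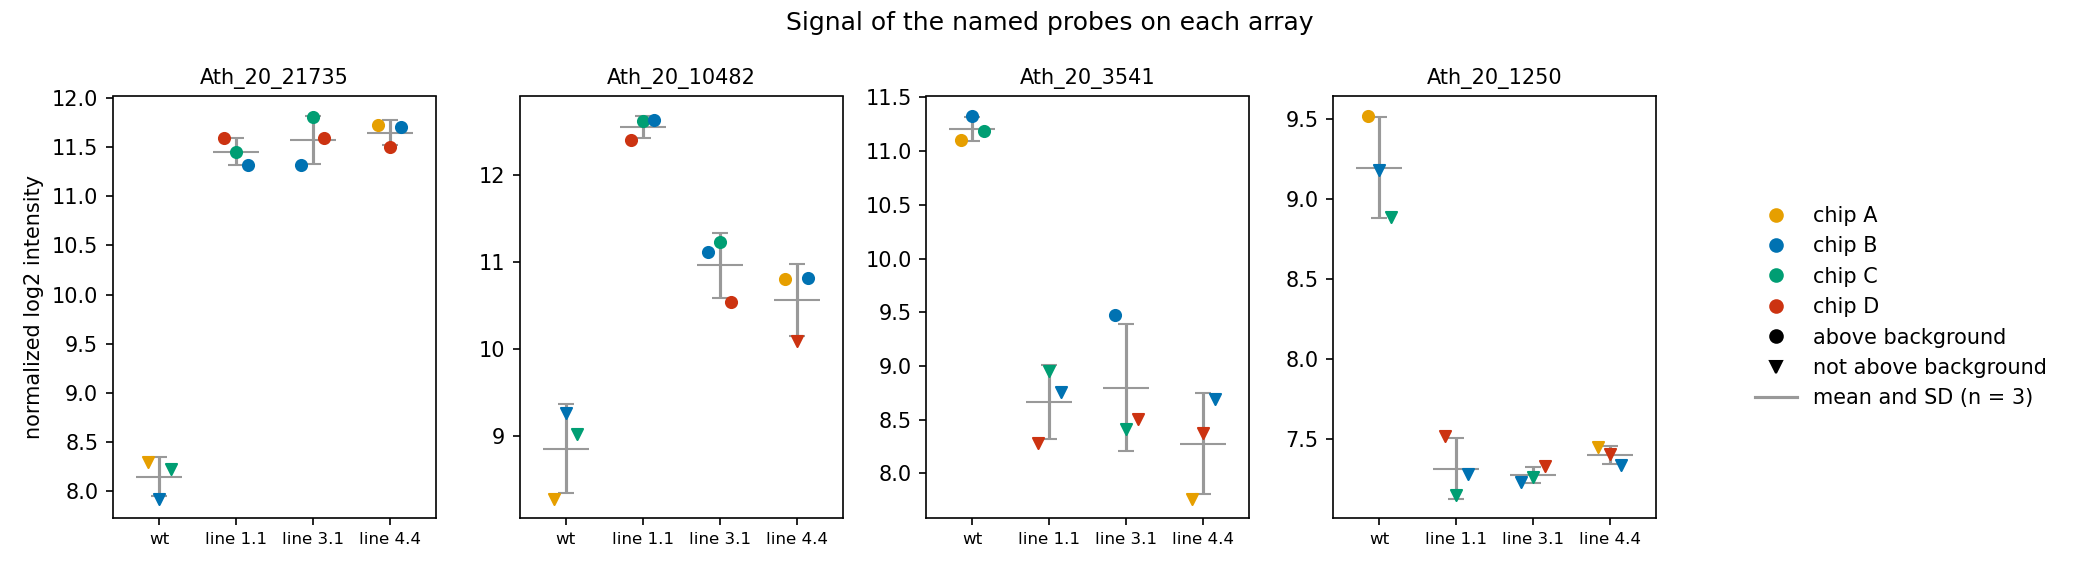
Normalized log2 intensity (vertical axis) of the 4 named probes on each of the 12 arrays by group (horizontal axis), coloured by chip, with circles for signals above background and triangles for those not above it. Grey bars give the mean and SD of 3 arrays; Ath_20_21735 stands near 11.56 in the overexpressors and 8.15 in wild type, and Ath_20_10482 is brightest in line 1.1.

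Line 1.1 differed from wild type at 96 probes (limma, adjusted p under 0.05), 35 of them higher and 61 lower. With 19 probes at their bound and 7 given no size, the median rise was 2.91-fold and the median fall 2.27-fold, and 68 of the 96 changed by at least 2-fold. Probe Ath_20_10482 had the largest fitted log2 fold change among the rises, 3.69 (SE 0.28, limma adjusted p = 0.000132). It was not above background in wild type, so its rise is a bound of at least 11.8-fold. Probe Ath_20_21735 rose by at least 6.02-fold (log2 fold change 3.31, SE 0.16), and probe Ath_20_3541 fell by at least 4.0-fold (log2 fold change -2.54, SE 0.30), being above background on none of the 3 arrays of the line. All 3 probes lay on the same side of every wild-type array in 3 of 3 arrays of the line, which the rule for naming them requires.

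With chip as a block, 148 probes were called in line 1.1, 64 higher and 84 lower, including 83 of the 96. The count was 16, 36 and 34 without wild-type replicates 1, 2 and 3, 35, 25 and 21 without replicates 1, 2 and 3 of the line, and 62 without replicate 2 of line 3.1. It was 21 with plain background subtraction, at which probes Ath_20_10482 and Ath_20_3541 were no longer called, 147 among the 11592 probes above background on at least 3 arrays, 271 with chip as a random block and 2760 with array weights. The excess of lower calls was not stable: 11 were higher and 5 lower without wild-type replicate 1, 21 and 14 without replicate 1 of the line, 14 and 7 without replicate 3 of the line, and 28 and 26 with only the groups compared.

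Line 3.1 differed from wild type at 47 probes (limma, adjusted p under 0.05), of which 33 were higher and 14 lower. With 11 probes at their bound and 1 given no size, the median rise was 2.55-fold and the median fall 2.24-fold, and 37 of the 47 changed by at least 2-fold. Probe Ath_20_21735 rose by at least 6.53-fold (log2 fold change 3.43, SE 0.16; limma adjusted p = 2.13e-06) and probe Ath_20_10482 by at least 3.93-fold (log2 fold change 2.1, SE 0.28; limma adjusted p = 0.0103). Probe Ath_20_3541 fell by at least 3.93-fold (log2 fold change -2.41, SE 0.30; limma adjusted p = 0.0102) and was above background on 1 of the 3 arrays of the line.

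In the fit with chip as a block, 61 probes were called in line 3.1, 42 higher and 19 lower, including 36 of the 47. The count was 16, 10 and 10 without wild-type replicates 1, 2 and 3, 21, 9 and 25 without replicates 1, 2 and 3 of the line, and 15 with plain background subtraction, at which the same probes were no longer called as in line 1.1. Array weights gave 666, of which 302 were higher and 364 lower, so the excess of higher calls was not kept there, and chip as a random block gave 158. Probe Ath_20_10482 lost its call in this line without wild-type replicate 3 or replicates 1 or 2 of the line (limma adjusted p = 0.0527, 0.0601 and 0.0882), and probe Ath_20_3541 lost it without wild-type replicates 2 or 3 or replicate 2 of the line (limma adjusted p = 0.0639, 0.0527 and 0.0809).

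Line 4.4 differed from wild type at 7 probes (limma, adjusted p under 0.05), 4 higher and 3 lower. Of these, 6 changed by at least 2-fold, 2 of them taken at their bound, and 1 is given no size. Probe Ath_20_21735 rose by at least 6.88-fold (log2 fold change 3.5, SE 0.16; limma adjusted p = 1.66e-06). Probe Ath_20_3541 fell by at least 3.38-fold (log2 fold change -2.93, SE 0.30; limma adjusted p = 0.00403), and probe Ath_20_1250 was called lower (limma adjusted p = 0.002) with no size given, as its bound is 0.839-fold. For probe Ath_20_10482 the log2 fold change was 1.71 (SE 0.28), which did not pass the test (limma adjusted p = 0.101).

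The fit with chip as a block called 9 probes in line 4.4, 6 higher and 3 lower, including 6 of the 7, and probe Ath_20_10482 then passed with a log2 fold change of 1.90 (limma adjusted p = 0.0132). Replicate 1 of this line had a narrower signal range than the other arrays, with a 95th percentile of 3.68 times its median against 5.98 to 8.36 times on the 11 others, and the count was 6 without it, 2 higher and 4 lower. At an unadjusted p under 0.05 limma gave 2184 probes in this line, against 1831 in line 1.1 and 1341 in line 3.1, and the median SD among its arrays was 0.31 log2 units, against 0.18 in both other lines. The fit shares 1 estimate of the spread over all groups, so the wider spread of this line can raise its 2184. These unadjusted counts therefore do not show a broader response. The count of calls at adjusted p under 0.05 was 3 with plain background subtraction and 4 with only this line and wild type in the fit, and it was 11 with loess, 20 with array weights and 30 with chip as a random block. Probe Ath_20_3541 lost its call with plain subtraction (limma adjusted p = 0.567, in a range of 0.000324 to 0.567 over the settings). Probe Ath_20_1250 lost it with only this line and wild type and with 75th percentile scaling (limma adjusted p = 0.0794 and 0.202, in a range of 1.29e-05 to 0.202). Without chip D and replicate 1 of the line, only 1 array of line 4.4 is left and is assumed to vary like the other groups; both probes missed the threshold there (limma adjusted p = 0.0946 and 0.074).

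**Figure D3:**
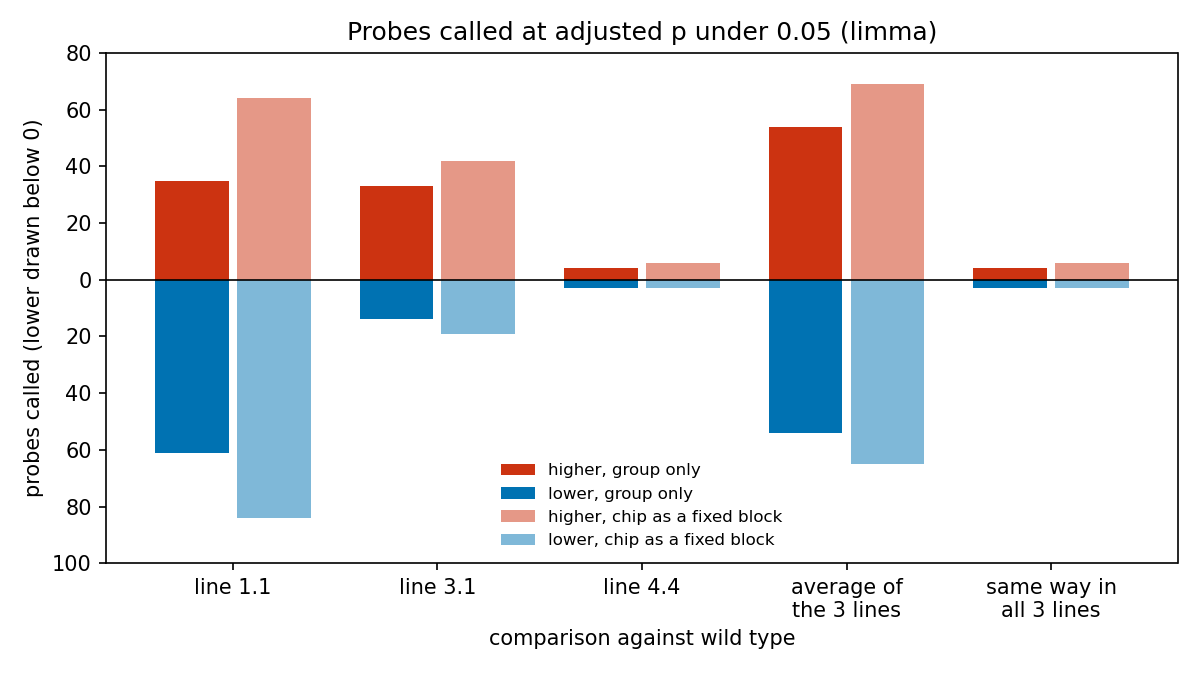
Number of probes called by limma (vertical axis, higher above the zero line and lower below it) for each comparison with wild type (horizontal axis), in the fit by group only (dark) and with chip as a block (pale). Line 1.1 has 96 and 148 calls in the respective fits, line 3.1 has 47 and 61, and line 4.4 has 7 and 9.

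All 7 probes called in line 4.4 were also called, with the same sign, in lines 1.1 and 3.1, so that 7 probes changed the same way in all 3 lines, 4 higher and 3 lower. The 6 of them that have a size in every line changed by 2.42-fold to 6.88-fold in single lines, with bounds used where they apply. They include Ath_20_21735, with bounds of 6.02-fold, 6.53-fold and 6.88-fold in lines 1.1, 3.1 and 4.4, and Ath_20_3541, while Ath_20_1250 is the probe with no size. Independent lists of the same lengths, which leave out the shared wild-type arrays, would share 9.32e-06 probes on average. Lists of the same lengths by smallest p, in 50 simulations of unchanged lines against shared wild-type arrays, shared 0.84 on average and 3 at most, and 0.78 and 4 with the estimated chip differences added. With chip as a block 9 probes were called in all 3 lines, 6 of them among the 7. The number was 4, 4, 4 and 3 without wild-type replicate 2, wild-type replicate 3, replicate 3 of line 1.1 and replicate 2 of line 3.1, in that order. It was 3 with plain background subtraction and 2 when each line was fitted with wild type alone, but 20 with array weights and 19 with chip as a random block.

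Lines 1.1 and 3.1 shared 21 higher and 8 lower calls, against 0.0416 and 0.0308 for independent lists, and 0 probes were called in opposite directions. Those 29 shared calls compare with 8.86 on average and 15 at most for lists of the same lengths by smallest p in 50 simulations of unchanged lines against shared wild-type arrays, and with 11.6 and 19 when the estimated chip differences were added. Part of the excess over independent lists may thus come from the shared wild-type arrays and the chips. Of the 96 probes called in line 1.1, 93 had the same sign in line 3.1 and 94 in line 4.4, and of the 47 called in line 3.1, 46 had it in line 1.1 and 45 in line 4.4. These shares (96.9%, 97.9%, 97.9% and 95.7%) lie near what the shared wild-type arrays give by themselves. In simulated unchanged lines the same numbers of probes with the smallest p had the same sign in 92.5%, 93.3%, 92.9% and 93.5% of cases, and in 97.0%, 93.5%, 97.9% and 94.2% with the estimated chip differences added. Across all probes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson's r of 0.720 for lines 1.1 and 3.1, 0.642 for lines 1.1 and 4.4, and 0.644 for lines 3.1 and 4.4, against a mean of 0.50 in 100 simulations of unchanged lines that share the wild-type arrays. The covariances were 0.0523, 0.0560 and 0.0489, against 0.0267, 0.0268 and 0.0267 in those simulations. With the estimated chip differences added, 50 simulations gave mean correlations of 0.701, 0.542 and 0.540 and covariances of 0.0398, 0.0290 and 0.0290. The covariance that shared wild-type arrays add was put at 0.0192 from the spread of the wild-type arrays and at 0.0313 from the unmoderated residuals of all groups, below the observed values. The 3 wild-type arrays cannot be parted into sets of at least 2, so no value from such separate sets is given. Same-chip differences taken from different wild-type arrays correlated between lines at 0.33 and 0.21 for lines 1.1 and 3.1, at -0.08, 0.06 and 0.08 for lines 1.1 and 4.4, and at -0.03, 0.06 and 0.62 for lines 3.1 and 4.4. Within the same line on different chips they correlated at 0.40 for line 1.1, 0.49 for line 3.1 and -0.18 for line 4.4. The low values with line 4.4 thus do not show that its response differs from that of the other lines.

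No probe differed among the 3 overexpressing lines in the moderated F test of limma (0 at adjusted p under 0.05, 883 at an unadjusted p under 0.05). The lowest adjusted p was 0.052. The count was also 0 with chip as a block, with 1396 at an unadjusted p under 0.05. For probe Ath_20_10482, which ranged over 1.98 log2 units between the line means, the adjusted p of this limma test was 0.0724, and 0.0597 with chip as a block. The probes called in line 1.1 or 3.1 and not in line 4.4 were therefore not shown to differ between lines. Other settings called between 0 and 112 probes, and the count was 3, 3 and 1 without replicate 3 of line 1.1, replicate 3 of line 3.1 and replicate 3 of line 4.4.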

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

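Chip as a random block, both settings without chip D, the pixel mean, and the spot median outside line 1.1 were chosen after seeing the data. Counts are given in the order line 1.1, line 3.1, line 4.4, average, all 3 lines and among lines, which were 96, 47, 7, 108, 7 and 0. Of 460 recomputed values of the named probes, 438 stayed on their side of the threshold, 18 lost the call and 4 gained it. Leaving out single arrays gave 16 to 132, 9 to 62, 5 to 9, 17 to 120, 3 to 9 and 0 to 3. Array weights gave 2760, 666, 20, 2238, 20 and 112, with weights from 0.145 for replicate 1 of line 4.4 to 11.8 for wild-type replicate 3. Chip as a random block gave 271, 158, 30, 233, 19 and 34. Chip as a fixed block gave 148 in line 1.1. Plain subtraction gave 21, 15, 3, 26 and 3. Percentile scaling gave 45 in the average and 11 among lines, and moved the median of all probes in line 4.4 to 0.13 log2 units. Loess gave 11 in line 4.4 and 1 among lines. The filter on dim probes, with fewer probes tested, gave 147 in line 1.1 and 14 among lines. The authors' table gave 71 in the average and 12 among lines. Fits with only the groups compared gave 54, 39, 4 and 2 for the lines and all 3 lines. Among lines, no background subtraction gave 7, the intensity trend 11 and the spot median 10. A minimum of 2-fold in the fitted values, without bounds, gave 57 in the average, and 1 mean per line as the replicate gave 45. Without chip D line 1.1 had 53, and without chip D and replicate 1 of line 4.4, which leaves line 4.4 with 1 array assumed to vary like the other groups, the counts were 94 in line 3.1, 3 in line 4.4 and 3 in all 3 lines. Where not stated otherwise the cause was not tested. The replicate number as a replicate block gave 49, 26, 7, 42, 5 and 5. Same-numbered arrays of different groups had correlated deviations from -0.65 to 0.60, over 0.1 in 7 of 18 pairs, and 5 of 12 arrays matched best with their own number. As many, 5 of 12, matched best with an array of their own chip, although levels differ between chips. A pairing by number was thus not seen, but it is not excluded. Only the groups compared gives no separate value for the average, and the gene list tests with their alternatives were not run. Signal limits the results, since 14616 probes exceeded background on no array.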

Other observations

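The ratios for single arrays of line 4.4, the GC test over brighter probes, the signal test on chips A to C, the control probes by chip, the calls under the chip block, the splits that follow a chip and the splits within chips were chosen only after results were seen. Over all probes, 4909 (17.7%) had no overlap between the arrays of line 1.1 and wild type, 3707 (13.4%) in line 3.1 and 2778 (10.0%) in line 4.4, against 10% by chance for 3 arrays against 3. For the 9 overexpressor arrays against wild type the number was 616 (2.22%), against 0.909% by chance. Of 114 probes called in at least 1 line, 85 were called in 1 line, 22 in 2 lines and 7 in 3 lines. The average of the lines added 31 probes called in no single line.

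The 7 probes called in all 3 lines included Ath_20_21735. Its line means differed by 0.19 log2 units, less than its SD of 0.20 among the wild-type arrays. Probe Ath_20_10482 is not among these 7 probes, and its line means spread over 1.98 log2 units. The limma adjusted p for a difference among lines ran from 0.0724 to 1 at these 7 probes. No line transformed with an empty vector is among the samples, so an effect of GmENOD40 and a difference between the wild-type stock and the transformed stock were not tested apart.

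The calls in the average of the lines were set against differences between chips, above all chip D, which carried 3 overexpressor arrays and no wild-type array. Without the arrays of chip D, 100% of the 108 probes kept at least 50% of their size in the same direction, but each line had 1 array on that chip, so an effect of chip D alone would have widened the spread within lines and kept a probe from being called, and this test decides nothing. The fit with chip as a block also called 85 of the 108, so at these 85 a difference from wild type remained with chip differences taken out. Their blocked log2 fold changes had a median ratio of 1.0 to the unblocked ones. That ratio decides nothing by itself, since the 108 calls were already selected against large differences between chips. The other 23 had a median ratio of 0.974, the lowest being 0.841, and a median standard error of 0.16 in place of 0.15. They missed the threshold with limma adjusted p up to 0.0963. Their kept sizes come from the same selected calls and the calls themselves were lost, so differences between chips stay open for these 23.

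Fewer probes were called in line 4.4 than in lines 1.1 and 3.1, and 2 explanations were weighed. Without replicate 1 of line 4.4, the array with the narrow range, 6 probes were called in place of 7, within the bound of 1.5 times set beforehand. Leaving out an array also removes a replicate. Line 1.1 fell from 96 calls to 35, 25 and 21 without its replicates 1, 2 and 3, and line 4.4 had 5 without replicate 2 and 5 without replicate 3. The count thus cannot decide about that array. The ratio described next was 0.548 for that array alone, against 0.592 and 0.511 for replicates 2 and 3. Smaller log2 fold changes on that array were therefore not seen, and its part in the spread was not tested. At the 114 probes called in line 1.1 or 3.1 the median ratio of the line 4.4 log2 fold change to that of the calling line was 0.539, between the bounds set for smaller responses and for equal ones, which leaves smaller responses open. Probes chosen for their size in 1 line tend to be smaller in another: the ratio of line 3.1 at the probes of line 1.1 was 0.700, and of line 1.1 at those of line 3.1 it was 0.905. At an unadjusted p under 0.05 line 4.4 had the most probes (2184, against 1831 and 1341), and its arrays had the widest median SD (0.31, against 0.18 in both other lines). With 1 estimate of the spread shared over all groups, that wider spread can raise the unadjusted count. A lower level of the transgene stays untested.

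Levels differed between chips at 4394 probes, with the widest differences on chip D (SD of 0.28 log2 units over probes). The chip D difference correlated with probe GC content at a Spearman's rho of 0.0773 across all probes, which are not independent replicates, under the bound of 0.1 set for excluding probe melting behaviour, but 14616 probes exceeded background on no array, and over probes above background on at least 3 arrays it was 0.130, so this stays open. With mean signal the rho was -0.000118 on chip D after quantile normalization, which removes such a trend, while the SD of 0.28 log2 units was left. The differences left on chip D in the normalized values thus followed no trend with signal. Since the normalization removes such a trend, this rho cannot decide whether signal level was their source. The -0.118 of chip A leaves a trend with signal open for the other chips. The 4394 probes are a count over all chips, against 3461 with 75th percentile scaling. With that scaling the rho was -0.661, 0.269, 0.478 and 0.195 on chips A, B, C and D, so before quantile normalization a trend with signal stays open. Of 125 control probes, 8 (6.4%) differed among chips, against 15.8% of Arabidopsis probes. No biological explanation was tested, since no group of the design follows the chips.

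Other divisions of the arrays were tried for each count. For line 1.1, line 3.1 and line 4.4 there are 10 splits of 6 arrays, too few for a share under 0.05; the real splits gave 96, 47 and 7 probes, each was the 1 split with as many, and the highest other count was 0 in each. For the average of the lines, 4 of 100 splits of the 12 arrays gave as many as the real 108, a share under 0.05, but these splits take no account of chip. The highest other split gave 5118 probes, several times the real count. It set the 3 arrays of chip D against the rest, which points to a structure of the arrays by chip. The 2 others, with 291 and 686 probes, had only arrays of chips A and D in the smaller set. Another split of that kind gave 0, and so did splits with 2 chip D arrays and 1 array of chip B or C there. These 2 splits thus do not add to that reading. In the splits made to follow a chip, chip C against the rest called 1 probe and chip D against the rest 4778, so this structure was seen for chip D and not for chip C. For probes changed the same way in all 3 lines, 2 of 100 splits gave at least 7, the other being the chip D split with 1315. The wild-type label was therefore also moved within chips A, B and C in the fit with chip as a block, which allows 24 splits. The real split was the 1 with as many calls in the average, 134 against 5 in the highest other, and the 1 with as many in all 3 lines, 9 against 1, but these 24 move line labels only by swapping them with wild type. In 100 splits that moved all labels within chips, the real one included, 3 gave at least 134 in the average, the highest other giving 371, and 3 gave at least 9 in all 3 lines, the highest other giving 12. Both shares are under 0.05. The other splits with at least 9 in all 3 lines kept the real wild-type arrays, and with other arrays as wild type the highest was 1. The split with 371 set other arrays as wild type, so a count in the average as large as the real one can also arise from another labelling within chips. For differences among lines the real count was 0, which each of 100 splits must reach, the highest giving 2503, so the splits decide nothing there.

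No control probe was called between any line or the average and wild type (limma, 0 of 125 at adjusted p under 0.05, 2 at an unadjusted p under 0.05 in the average). Among them the factory control NC-plant-6 ranged from 789 to 5501 in raw intensity and NC-plant-7 from 1458 to 9261 over the 12 arrays.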
